A study of Mus musculus with 10 samples.

How the data were processed

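RNA of left ventricular tissue was sequenced from 10 mouse samples, 5 labelled as TAC with placebo and 5 as TAC with osimertinib, and each sample's group and number were taken from its title. The label of the placebo samples gives their treatment as vehicle. RNA was extracted with a column kit and selected for poly(A) tails with oligo(dT) beads from 5 ug of total RNA, per the labels' protocols, and the libraries kept strand, per the design text.

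The deposited values are CPM, one value per gene and library, which the authors scaled to each library's own total, and every column sums to 1000000. No factor between libraries was applied to the deposited CPM. Per the design text, reads were aligned to the mouse genome and transcriptome (GRCm38) with STAR and quantified with RSEM through the nf-core RNA-seq pipeline, and the authors tested genes with limma and voom. Versions of these tools are not given in the sources used here. The submitters' processing notes name other tools, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and DESeq2, and the human build hg38. The gene identifiers are mouse identifiers, of which 98.8% (45143 of 45706) matched the GENCODE M21 annotation of GRCm38, which gave symbols and coordinates.

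The spacing of low values gave the CPM worth of 1 read in each library and so its depth, between 15863265 and 21309296 reads. Values under 200 reads were multiples of 0.01 read in 100% of cases and whole reads, to a tolerance of 0.01 read, in 90.49% to 93.02%, as estimated counts that divide reads between genes would be. Because the reads did not come out whole for nearly all genes, the count tests planned for whole reads were not run. Voom on the estimated reads was added after the data were examined. A gene with 0 reads is given an upper limit of 3 reads. No pair among 45 pairs of libraries agreed within sampling noise (lowest chi-square per degree of freedom 23.9), and Pearson correlations within a group lay between 0.943 and 0.989.

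Genes with at least 1 CPM in at least 5 of the 10 libraries were tested (12350 genes). The test was limma with an intensity trend on log2(CPM + 0.5), two-sided, with Benjamini-Hochberg adjustment and calls at 0.05, so that fold changes are on the log2(CPM + 0.5) scale, which understates changes of low genes. SE is the moderated standard error. The variance shared between genes weighed heavily in the deposited CPM, with a prior of 72.9 degrees of freedom against 4.45 after rescaling, and the median SE was 0.311 against 0.157. In the deposited CPM the prior was infinite in the fits without placebo library 1, 3 or 4 or osimertinib library 2, 3, 4 or 5. A gene's own spread does not enter its SE in those fits, so their calls rest on the shared variance. Median-ratio rescaling divided each library by its median ratio to the geometric mean library over tested genes, by 0.4545 for placebo library 5 and by 0.9257 to 1.344 for the other 9.

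Before the data were examined, 40 gene lists were fixed, and 37 had the 4 tested members required. Lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated per list and with fry, adjusted over the lists. Each list is given with its number of called members over all genes tested and adjusted over the list alone. The 4 composition measures and the first 3 principal components were tested with the exact permutation test over 252 assignments, two-sided, whose smallest p is 0.00794. Genes of chromosome 1 sharing at least 50% of their 31-base words with mitochondrial transcripts were counted as nuclear copies. Reads of near-identical genes are uncertain.

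The rule for the named genes was also fixed before the data were examined. It took the 10 largest rises and falls among called genes with a mean of at least 2 CPM in the higher group and all samples of a group on one side of the other group's mean, the 5 lowest p in each direction, up to 4 members of each called list and, called or not, of the stress, extracellular matrix, calcium handling, ion channel, deacetylase, ErbB, fatty acid oxidation and oxidative phosphorylation lists, and 24 genes fixed by name, of which 1 is not reported here. Clone names, pseudogenes and unnamed genes were left out. Its use on the rescaled values was added later, and the text says where a gene was picked after its values were seen.

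Settings varied, as chosen before the data were examined, were pseudocounts of 0.1 and 2, no filter, a mean of at least 5 CPM, rescaling, quantile normalization, CPM without mitochondrial and haemoglobin genes, no trend, array weights, the replicate number as a block, and leaving out each library. Chosen after the data were examined were rescaling without placebo library 5, with atrial transcripts as a covariate, with the block and with a correction for transcript length and GC content, voom on estimated reads, CPM without mitochondrial genes, their nuclear copies and haemoglobin genes, and the fits and cell marker scores that leave out a library after rescaling. The fits were tested on simulated data for this comparison, drawn at a dispersion of 0.05 with 200 genes changed and 12388 genes tested. They recovered 88% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, with 6 false calls among 12112 unchanged genes as deposited and 8 after rescaling. The simulation gave every library the same mean profile and drew genes independently. It held none of the differences between libraries in mitochondrial share or atrial transcripts, so these rates need not hold for the real data. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.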

Results

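Messenger RNA was profiled in left ventricular tissue of mouse hearts after transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. The 10 libraries fell into 2 groups of 5, hearts given placebo and hearts given osimertinib, an inhibitor of the epidermal growth factor receptor tyrosine kinase used against lung cancer. The study asked what underlies the cardiac toxicity of osimertinib, and its title names histone deacetylases, so these enzymes and the receptors of the drug's target family are reported whatever their test gave. The deposited values were CPM, read counts scaled to a total of 1000000 per library, for 45706 genes, of which 24084 were at 0 in every library. Depth recovered from the spacing of the values lay between 15863265 and 21309296 reads per library. The labels do not say that the samples of a group came from separate animals, so the p-values measure only the spread between these samples.

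Mitochondrially encoded genes took 46.8% ± 9.97 (SD, n = 5) of the reads in placebo and 37.0% ± 5.22 (n = 5) in osimertinib, with 5 of 5 osimertinib samples under the placebo mean. This difference did not pass the exact permutation test (two-sided p = 0.0714, adjusted p = 0.0952 over 4 measures). The placebo mean was raised by placebo library 5, at 63.35%. The other placebo libraries lay between 38.1% and 48%, and the osimertinib libraries, between 31.75% and 45.2%, overlapped them. A further 15.7% ± 2.42 of placebo reads and 13.4% ± 0.963 of osimertinib reads lay on 7 genes of chromosome 1 that share 97.2% to 100% of their 31-base words with mitochondrial transcripts, so the division of reads between these genes and the mitochondrial genome is uncertain. The placebo library 5 stood apart, with 83.0% of its reads on mitochondrial genes and these copies, against 45.1% to 63.7% in the other 9. The share of the 10 highest genes (57.6% ± 11.7 against 46.0% ± 5.64, exact p = 0.0556) and that of ribosomal protein genes (1.29% ± 0.296 against 1.57% ± 0.106, exact p = 0.0397) both came to an adjusted p of 0.0952 over the 4 measures. Without placebo library 5 the difference in percentage points moved from -9.79 to -5.65 for mitochondrial genes, from -11.6 to -6.74 for the 10 highest genes and from 0.283 to 0.162 for ribosomal protein genes (adjusted p = 0.18 for each). Haemoglobin genes held 0.0316% ± 0.0173 and 0.0319% ± 0.0234 (exact p = 0.96).

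**Figure D1:**
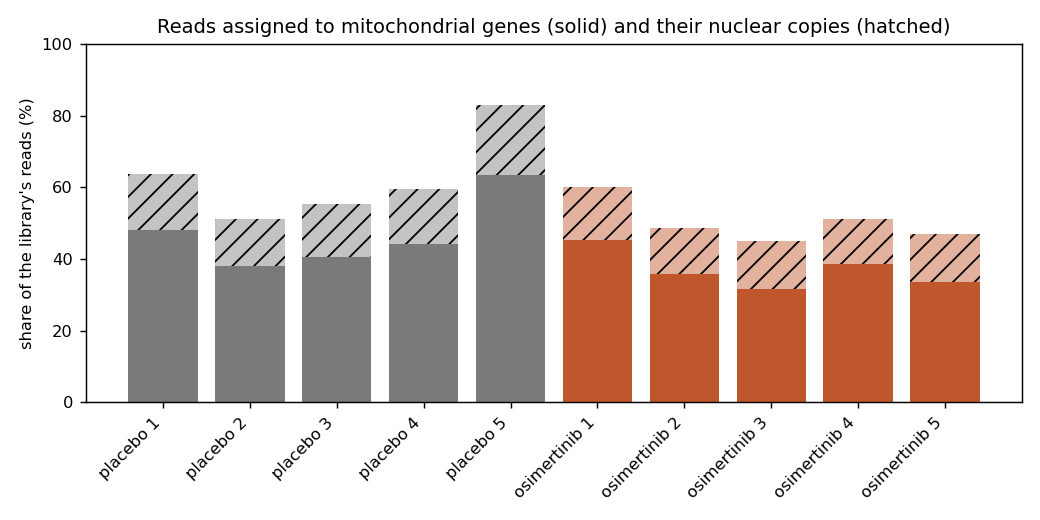
Share of each library's reads (%) on mitochondrially encoded genes (solid bars) and on their 7 nuclear copies (hatched), with placebo in grey and osimertinib in orange. The placebo library 5 reaches 83.0% and the other 9 lie between 45.1% and 63.7%.

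The deposited CPM carry no scaling between libraries. The median log2 fold change of the 12350 genes tested was 0.27 in the deposited CPM and 0.01 after median-ratio rescaling, and values after rescaling are named as such. In the deposited CPM 833 genes passed limma with Benjamini-Hochberg adjustment at 0.05, of which 817 were higher and 16 lower in osimertinib. After rescaling 2574 passed, 1283 higher and 1291 lower. Both scalings shared 630 of the higher and all 16 of the lower genes, and no gene was called in opposite directions. The count in the deposited CPM fell to 397 without placebo library 1, 510 without osimertinib library 2, 307 without osimertinib library 3 and 343 without osimertinib library 5. Without placebo library 5 it was 805, with 567 higher and 238 lower. With no filter on low values no gene passed limma, at a smallest adjusted p of 0.0707 and with 3269 of 21622 genes at an unadjusted p under 0.05. The rescaled count was 878 without placebo library 1, 810 without placebo library 2, 512 without osimertinib library 3 and 690 without osimertinib library 5.

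Many nuclear genes of mitochondrial energy metabolism rose in osimertinib. Of 18 genes of the tricarboxylic acid cycle, 17 rose over all genes tested both in the deposited CPM and after rescaling, with a median log2 fold change of 1.40 (1.12 rescaled). Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase (chromosome 7, 80094846 to 80115392, GRCm38), stood at 444 ± 250 CPM (SD, n = 5) in placebo and 1367 ± 557 in osimertinib. Its log2 fold change was 1.77 ± 0.35 (SE), with a limma adjusted p of 0.00251, and 1.48 ± 0.36 after rescaling (adjusted p = 0.0209). Fh1, the fumarase of the cycle, rose by 1.69 ± 0.35 (1.40 ± 0.31 rescaled). Fatty acid oxidation had 21 of 30 genes higher (13 rescaled) and a median of 1.25 (0.98 rescaled), and among them were the dehydrogenase Acadl (1.65 ± 0.35, adjusted p = 0.00363) and the trifunctional protein subunit Hadhb (1.71 ± 0.36, adjusted p = 0.00332). Of 77 nuclear genes of oxidative phosphorylation, 41 rose (24 rescaled), including the complex II subunit Sdha (1.53 ± 0.34) and the ATP synthase subunit Atp5a1 (1.59 ± 0.34), and the list median was 1.07 (0.79 rescaled). Branched-chain amino acid catabolism had 14 of 17 genes higher under both scalings, Pcca among them at 1.51 ± 0.32, and a median of 1.12 (0.84 rescaled). Each gene named here was above the placebo mean in 5 of 5 osimertinib samples and passed in each of 10 fits that left out 1 library of the deposited CPM. Most of these fits had an infinite prior, under which a gene's own spread does not count. The lists varied within placebo, scored as mean log2 rescaled and centred over the 10 libraries. Oxidative phosphorylation stood at -1.14, -0.65, 0.31, 0.27 and -0.74 in placebo libraries 1 to 5, against 0.06 to 0.86 in osimertinib. Fatty acid oxidation and branched-chain amino acid catabolism also overlapped between the groups. The tricarboxylic acid cycle list did not, at -0.0018 or less against 0.02 or more. In the rescaled values Idh2, Atp5a1 and Hadhb were lost without placebo library 1 or 2 or osimertinib library 3 or 5 (adjusted p up to 0.0734). Acadl was lost without placebo library 2 or osimertinib library 3 or 5 (up to 0.057) and Sdha without osimertinib library 3 (0.0503).

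Adjusted over the list alone, all 18 tricarboxylic acid cycle genes, 24 fatty acid oxidation genes, 66 oxidative phosphorylation genes and all 17 genes of branched-chain amino acid catabolism passed (17, 23, 52 and 15 rescaled). Camera at a preset correlation called 19 of 37 lists, 16 higher and 3 lower, a number that 50 of 100 splits of the samples, the real one included, also reached. It called the 4 metabolic lists higher, with adjusted p of 3.5e-19, 2.1e-16, 1.3e-27 and 4.3e-12. None was called with a correlation estimated per list, at an adjusted p of 0.56 with an estimated correlation for each. The 13 mitochondrially encoded messenger RNAs lay the other way, at a list median of -0.32 (-0.61 rescaled) and a camera adjusted p of 1.3e-06 (adjusted p = 0.56 with an estimated correlation), but none of them passed by itself, with mt-Nd2 at -0.48 ± 0.29 (adjusted p = 0.353) and mt-Nd3 at -0.43 ± 0.31 (adjusted p = 0.457). Glycolysis and glucose uptake had 9 of 21 genes higher (10 rescaled, 14 adjusted over the list alone), with Pgk1 at 1.37 ± 0.34 and a camera adjusted p of 1.3e-06 (adjusted p = 0.734 with an estimated correlation). Mitochondrial biogenesis and dynamics had 6 of 19 higher (7 higher and 1 lower rescaled, 9 adjusted over the list alone), with Esrrg at 1.09 ± 0.31, while Ppargc1a, a coactivator of mitochondrial biogenesis, was at 0.91 ± 0.34 (adjusted p = 0.0845, and 0.00563 at its lowest among fits without 1 library, of which those without placebo library 3 or osimertinib library 1 called it). The camera adjusted p of the biogenesis list was 0.0106 (adjusted p = 0.756 with an estimated correlation). Without placebo library 5 the list was no longer called (0.0537), and the call of Esrrg was lost without placebo library 1 or 5 or osimertinib library 3 or 5 (adjusted p up to 0.0907). After rescaling Esrrg held in 4 such fits, those without placebo library 3 or 4 or osimertinib library 1 or 4 (up to 0.0967 in the rest), and Pgk1 was lost without placebo library 2 or osimertinib library 3 or 5 (up to 0.0605). The rescaled fit without placebo library 3 called Ppargc1a (0.0159).

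**Figure D2:**
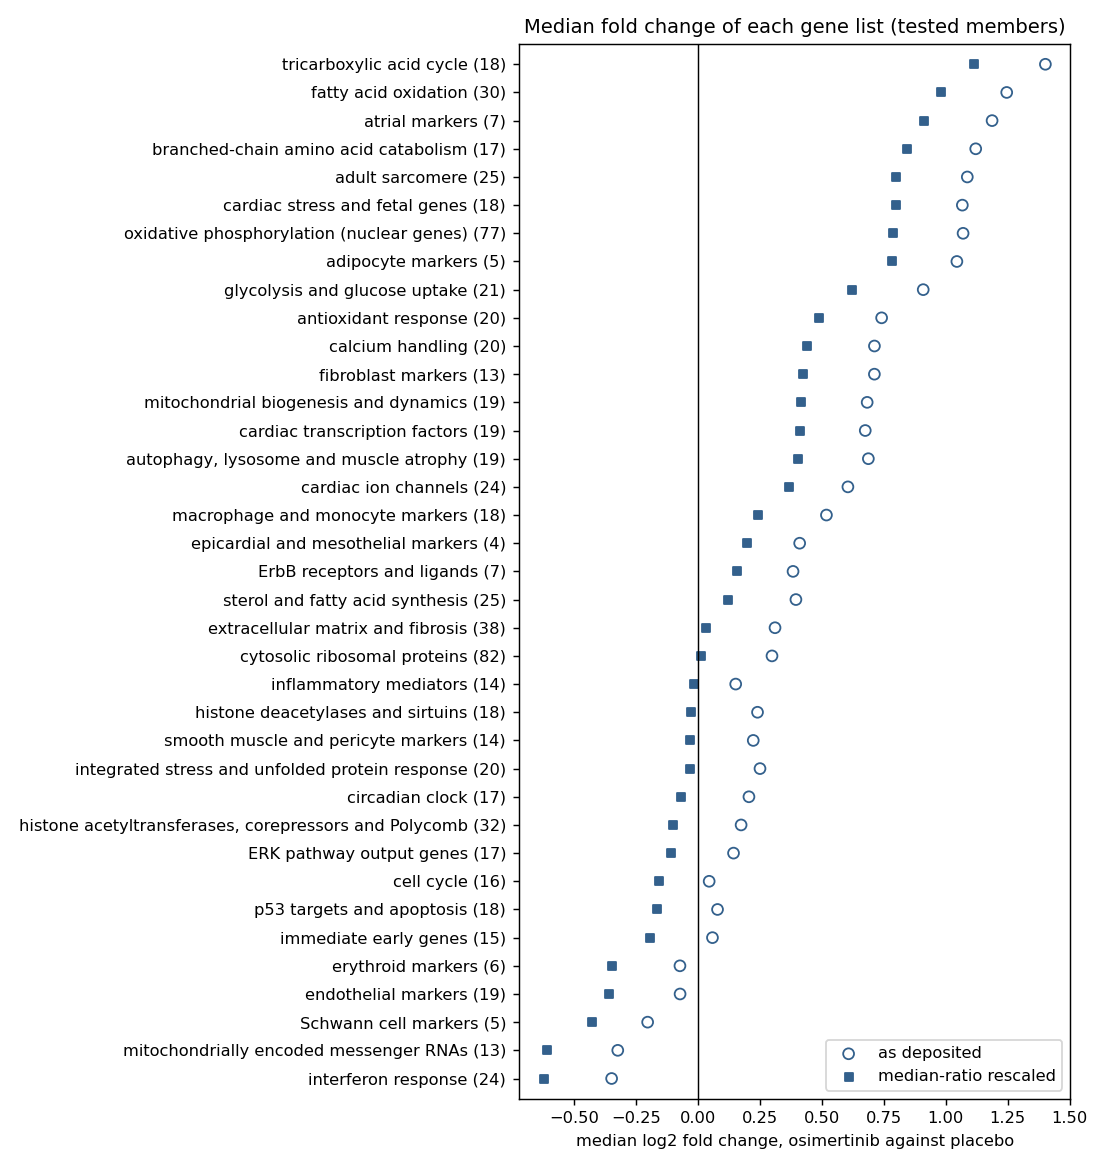
Median log2 fold change (osimertinib against placebo, x axis) of the tested members of each gene list, with the number tested in parentheses. Open circles are the deposited CPM and filled squares the rescaled values, and the tricarboxylic acid cycle reaches 1.40 and 1.12 at the top while the interferon response lies at -0.35 and -0.62 at the bottom.

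Some genes of the contractile apparatus and its regulation were also higher. Of 25 adult sarcomere genes, 14 were higher (12 rescaled, 20 adjusted over the list alone), with a median of 1.09 (0.80 rescaled), among them cardiac actin Actc1 at 1.76 ± 0.35 and the M-band protein gene Myom2 at 1.70 ± 0.35 (adjusted p = 0.00295). The alpha myosin heavy chain Myh6 was at 0.59 ± 0.31 (adjusted p = 0.263). Of 20 calcium handling genes 4 rose, with 9 adjusted over the list alone, and after rescaling 4 were higher and 1 lower, the calcium channel gene Cacna1c at -0.47 ± 0.11. Atp2a2, the calcium pump of the sarcoplasmic reticulum (chromosome 5, 122453513 to 122502225), went from 1050 ± 481 to 2537 ± 680 CPM, a log2 fold change of 1.38 ± 0.34 (adjusted p = 0.00823) and 1.09 ± 0.28 rescaled. Its inhibitor Pln rose by 1.27 ± 0.34, and the ryanodine receptor gene Ryr2 was at 0.82 ± 0.34 (adjusted p = 0.133). Without placebo library 5 Ryr2 was at 0.48, and rescaled fits without placebo library 4 or osimertinib library 1 called it (0.034 at the lowest). Of 24 ion channel genes 6 rose, with 10 adjusted over the list alone, among them Kcnq1 (1.13 ± 0.30), Kcnj5 (1.68 ± 0.31) and Scn4b (1.52 ± 0.32). After rescaling 6 were higher and 1 lower, Kcnd3 at -0.55 ± 0.17; Cacna1c and Kcnd3 were picked after their values were seen. The potassium channel gene Kcnh2 (0.25 ± 0.32, adjusted p = 0.717, and -0.04 rescaled) did not pass. Of 19 cardiac transcription factors 5 rose (6 rescaled, 9 adjusted over the list alone), including Nkx2-5 at 1.48 ± 0.32, Tbx20 at 1.39 ± 0.31 and Gata4 at 1.01 ± 0.31. In the deposited CPM the call of Kcnq1 was lost without osimertinib library 3 (adjusted p = 0.0706), that of Pln without placebo library 1 or 5 or osimertinib library 3 or 5 (up to 0.0645). That of Gata4 was lost in 6 of the 10 fits without 1 library (up to 0.134), those without placebo library 1 or 4 or osimertinib library 2, 3, 4 or 5. After rescaling Actc1 was lost without placebo library 1, 2 or 5 or osimertinib library 3 or 5 (up to 0.0821). Atp2a2 was lost without placebo library 1 or 2 or osimertinib library 3 or 5 (up to 0.071). Pln held without placebo library 3 or 4 or osimertinib library 1 or 4 (up to 0.107 in the rest), and Scn4b was lost without osimertinib library 3 (0.059). Cacna1c was lost without placebo library 2 or osimertinib library 3 or 5 (up to 0.0591), and Kcnd3 in all but the fits without placebo library 3 or osimertinib library 2 or 4 (up to 0.11). The ion channel list was no longer called after rescaling (camera adjusted p = 0.057) or without placebo library 5 (0.0775).

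The cardiac stress and fetal genes, which rise in loaded or failing ventricles, had 7 of 18 members higher in the deposited CPM (12 adjusted over the list alone) and 2 after rescaling, Ankrd1 and Fhl1 (0.57 ± 0.13 rescaled), the latter picked after its values were seen and lost without osimertinib library 3 (0.0569). Ankrd1, a stress-responsive sarcomere gene (chromosome 19, 36111961 to 36120099), rose from 315 ± 210 to 904 ± 218 CPM, by 1.77 ± 0.35 on the log2 scale (limma adjusted p = 0.00245) and by 1.49 ± 0.32 rescaled (adjusted p = 0.0161). Skeletal actin Acta1, the natriuretic peptide genes Nppa and Nppb and the beta myosin heavy chain Myh7 passed in the deposited CPM, at 1.86 ± 0.43, 1.19 ± 0.35, 1.58 ± 0.40 and 1.47 ± 0.36. They did not pass after rescaling, where their adjusted p were 0.114, 0.0543, 0.0847 and 0.0854. Some rescaled fits without 1 library called them, Acta1 and Nppb without placebo library 3 or osimertinib library 4 (0.0162 and 0.0165 at the lowest), Nppa without placebo library 3 or osimertinib library 5 (0.0295) and Myh7 without osimertinib library 4 (0.0433). Without placebo library 5 none of these 4 passed in the deposited CPM (adjusted p up to 0.14), and Acta1 was also lost without placebo library 2 and Nppa without osimertinib library 3 or 4. The atrial genes Myl7 and Myl4, which are also on this list, and Nppa are abundant in atrial muscle, and atrial transcripts were high in 6 of the 10 libraries. The 7 atrial markers tested had 2 members higher in the deposited CPM (2 adjusted over the list alone), Nppa and, picked after its values were seen, Dkk3 at 1.59 ± 0.52, none after rescaling, and a camera adjusted p of 0.206. The call of Dkk3 was lost without placebo library 2, 4 or 5 or osimertinib library 4 (adjusted p up to 0.209), and the list was called without placebo library 1 (5.6e-13), osimertinib library 3 (5.2e-17) or osimertinib library 5 (6.6e-19). The fits without these 3 libraries also called Myl7 and Myl4, whose adjusted p in all 10 libraries were 0.534 and 0.421. The prior was infinite in those fits, so the spread of Myl7 and Myl4 themselves did not enter these calls. Camera called the sarcomere (1.8e-12), calcium handling (0.00227), ion channel (0.0121), transcription factor (0.0034) and stress (8.8e-06) lists higher. With an estimated correlation the adjusted p was 0.56 for the sarcomere and stress lists and 0.756 for the other 3.

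Antioxidant genes had 4 of 20 members higher (6 rescaled, 11 adjusted over the list alone), among them the quinone reductase Nqo1 at 1.62 ± 0.32 and the mitochondrial peroxiredoxin Prdx3 at 1.56 ± 0.34. The list of autophagy, lysosome and muscle atrophy had 4 of 19 higher (8 rescaled, 8 adjusted over the list alone), including the muscle ubiquitin ligase gene Fbxo32 at 1.41 ± 0.33 and Map1lc3a at 1.39 ± 0.34. Camera adjusted p were 6.2e-05 and 9.3e-05 (adjusted p = 0.753 and 0.756 with an estimated correlation). After rescaling Prdx3 was lost without osimertinib library 3 or 5 (up to 0.0576) and Map1lc3a without placebo library 2 or osimertinib library 3 or 5 (up to 0.0623).

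The interferon response was the pathway list with the lowest median, at -0.35 in the deposited CPM and -0.62 rescaled. None of its 24 members passed in the deposited CPM, alone or adjusted over the list alone, whereas 17 fell after rescaling (19 adjusted over the list alone). Stat2, which carries interferon signals to the nucleus (chromosome 10, 128270559 to 128292849), was at 50.6 ± 20.3 CPM in placebo and 29.4 ± 9.58 in osimertinib. Its log2 fold change was -0.73 ± 0.33 (adjusted p = 0.169), and -1.01 ± 0.21 after rescaling (limma adjusted p = 0.0141), with 5 of 5 osimertinib samples below the placebo mean. The antiviral gene Mx2 was at -0.57 ± 0.30 and -0.80 ± 0.18 rescaled (adjusted p = 0.0181). Camera called the list lower, with an adjusted p of 9.2e-11 in the deposited CPM (adjusted p = 0.56 with an estimated correlation) and 5.0e-10 rescaled (adjusted p = 0.578 with an estimated correlation). The call of Mx2 was lost after rescaling without osimertinib library 3 (0.0549), and Stat2 was called in the deposited CPM without placebo library 5 (0.0396). Fry, which asks whether a list moves on balance one way, gave it an adjusted p of 0.48 in the deposited CPM and 0.0176 rescaled. Fry called no list in the deposited CPM (lowest adjusted p = 0.16) and 6 after rescaling. Those called lower were the interferon, endothelial and acetyltransferase lists (0.0176 for each), and those called higher were transcription factors (0.00216), autophagy (0.0176) and branched-chain amino acid catabolism (0.0499).

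Few markers of the other cell types of the heart passed in the deposited CPM. Of 19 endothelial markers none passed in the deposited CPM, alone or adjusted over the list alone, and 8 fell after rescaling (8 adjusted over the list alone), among them the transcription factor gene Sox17 (-0.61 ± 0.32, and -0.89 ± 0.12 rescaled, adjusted p = 0.00868) and Robo4 (-0.48 ± 0.33, and -0.77 ± 0.11 rescaled). Both passed in the deposited CPM without placebo library 5 (0.0234 and 0.0308). Vwf, another endothelial gene, was at 0.63 ± 0.32 (adjusted p = 0.244). The camera adjusted p of the list was 6.2e-04 (adjusted p = 0.756 with an estimated correlation). Of 13 fibroblast markers 1 rose (2 rescaled, 5 adjusted over the list alone), Gsn at 1.15 ± 0.33, while Clec3b passed after rescaling (0.66 ± 0.14, adjusted p = 0.0148) and not in the deposited CPM (adjusted p = 0.0533), except without placebo library 2 or 5 or osimertinib library 1. Of 18 macrophage and monocyte markers 1 rose (3 higher and 1 lower rescaled, 2 adjusted over the list alone), Cx3cr1 at 1.16 ± 0.30, with Adgre1 at 0.86 ± 0.29 (adjusted p = 0.0557), which passed without placebo library 2 or 5 and after rescaling (0.60 ± 0.19, adjusted p = 0.0437). After rescaling 1 of the 10 fits without 1 library called Gsn and Adgre1, that without placebo library 5 (adjusted p up to 0.103 for Adgre1), and 2 called Cx3cr1, those without placebo library 5 or osimertinib library 4 (adjusted p up to 0.106 and 0.097). Of 5 adipocyte markers 1 rose, Cidec (0 rescaled, 3 adjusted over the list alone). Camera called these 3 lists higher, at adjusted p of 0.0134, 0.0384 and 0.0246 (0.756, 0.756 and 0.56 with an estimated correlation), and no longer called the adipocyte list after rescaling (0.378). Without osimertinib library 4, which had 3668 CPM of Gsn against at most 1573 in the other osimertinib libraries, Gsn (adjusted p = 0.152) and the fibroblast, macrophage and adipocyte lists (0.192, 0.192 and 0.114) no longer passed. The macrophage list was also lost without placebo library 1 or 4 or osimertinib library 1 (0.142, 0.0842 and 0.122). The adipocyte list was lost without placebo library 2 or 5 or osimertinib library 1 (0.498, 0.0791 and 0.104) and Cidec without placebo library 2 or 5 or osimertinib library 1 or 4 (adjusted p up to 0.137).

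The drug's target Egfr (chromosome 11, 16752203 to 16918158) was at 3.82 ± 1.66 CPM in placebo and 5.06 ± 2.29 in osimertinib, a log2 fold change of 0.42 ± 0.32 (adjusted p = 0.475), and Erbb2 and Erbb3 were at 0.13 ± 0.31 and 0.43 ± 0.31, with Erbb2 turning to -0.14 after rescaling. Without placebo library 5 these 3 were at 0.09, 0.0026 and 0.17, and without osimertinib library 4 Egfr was at 0.20. Erbb4, a neuregulin receptor gene, rose by 1.14 ± 0.32 (adjusted p = 0.0199, and 0.98 ± 0.30 rescaled) from a low level of 0.856 ± 0.556 CPM, and was the member called among 7 tested genes of the family (1 adjusted over the list alone). Its call was lost without placebo library 5 or osimertinib library 4 (adjusted p up to 0.135). After rescaling it held in the fits without placebo library 4 or osimertinib library 1 or 4 (up to 0.0843 in the rest). Nrg1 was under the filter on low values and was not tested. Of 18 histone deacetylases and sirtuins 2 rose, Hdac11 (0.94 ± 0.29, adjusted p = 0.0379) and the mitochondrial sirtuin gene Sirt5 (1.24 ± 0.32, adjusted p = 0.00979), and both also passed adjusted over the list alone and after rescaling. Of the 10 fits without 1 library of the deposited CPM, 3 called Hdac11 (those without placebo library 2 or 5 or osimertinib library 1, adjusted p up to 0.138 in the rest) and all but that without osimertinib library 3 called Sirt5 (0.0582). After rescaling Hdac11 passed in 4 such fits, those without placebo library 4 or 5 or osimertinib library 1 or 2, and Sirt5 in 5, those without placebo library 3 or 4 or osimertinib library 1, 2 or 4 (up to 0.107 and 0.0814 in the rest). Hdac1, Hdac2, Hdac3, Hdac4, Hdac5 and Hdac9 had adjusted p between 0.437 and 0.996 in the deposited CPM, and Hdac5 turned from 0.19 to -0.10 with rescaling. The rescaled fit without placebo library 3 called Hdac1 (limma adjusted p = 0.0405). Hdac6 was at -0.21 ± 0.31 (adjusted p = 0.762) in the deposited CPM and -0.48 ± 0.09 after rescaling (adjusted p = 0.0132). It was 1 of 5 members that passed as lower then, with Hdac7, Hdac10, Sirt1 and Sirt7 (-0.43 ± 0.12, -0.59 ± 0.14, -0.52 ± 0.12 and -0.63 ± 0.16), which were picked after their values were seen. After rescaling Hdac6 passed in each of the 10 fits without 1 library, Hdac10 and Sirt1 in all but that without osimertinib library 3 (0.0562 for both). Hdac7 was lost without placebo library 1 or 2 or osimertinib library 3 or 5, and Sirt7 without placebo library 2 or osimertinib library 3 or 5 (up to 0.0809 and 0.0661). Neither list was called by camera (adjusted p = 0.538 for the ErbB family and 0.699 for deacetylases and sirtuins).

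None of the 38 extracellular matrix and fibrosis genes passed in the deposited CPM, alone or adjusted over the list alone, and 1 was lower after rescaling, Col6a3 (-0.69 ± 0.20), picked after its values were seen. Its call held without placebo library 4 or 5 or osimertinib library 1 or 4 (up to 0.0871 in the rest). The collagen genes Col1a1 and Col3a1 were at 0.64 ± 0.34 and 0.59 ± 0.34, Postn at -0.06 ± 0.37 and the matrix signalling gene Ccn2 at 1.05 ± 0.36 (limma adjusted p = 0.262, 0.322, 0.947 and 0.0611), and Ccn2 passed without placebo library 1 or 3 (0.00456 at its lowest). The rescaled fit without placebo library 3 also called Ccn2 (0.0312). The list's median lay 0.04 above that of all genes while camera's direction was down, at an adjusted p of 0.985, and up after rescaling (0.928). Without placebo library 1 or osimertinib library 5 the list was called higher (0.0415 and 0.0463). The circadian clock list (camera adjusted p = 0.0874) had 1 of 17 genes lower (1 adjusted over the list alone), Per2 at -0.98 ± 0.32 (adjusted p = 0.0459, and -1.25 ± 0.28 rescaled), a call that 3 of the 10 fits without 1 library of the deposited CPM kept, those without placebo library 5 or osimertinib library 2 or 4. After rescaling 2 genes of the list were lower. The 32 histone acetyltransferase, corepressor and Polycomb genes had 1 member higher in the deposited CPM, Rbbp7 at 1.01 ± 0.32 (0 adjusted over the list alone), and 2 higher and 4 lower after rescaling (the same counts adjusted over the list alone). Their camera adjusted p was 0.281. The 18 p53 and apoptosis genes had 1 higher, Ccng1 at 1.18 ± 0.33 (1 adjusted over the list alone), and 0.277, and the 4 epicardial markers 1 higher, Gpm6a at 1.16 ± 0.32 (1 adjusted over the list alone), and 0.742. After rescaling the p53 list had 1 higher (2 higher and 3 lower adjusted over the list alone). Over all genes Gpm6a then did not pass, there or in any rescaled fit without 1 library (adjusted p from 0.0618). The epicardial list then had 0 higher and 1 lower (1 higher and 1 lower adjusted over the list alone). These 3 genes were picked after their values were seen. Rbbp7 was lost without placebo library 1 or 4 or osimertinib library 2, 3, 4 or 5, Ccng1 without placebo library 1 or osimertinib library 3 or 5, and Gpm6a without placebo library 3 or 5 or osimertinib library 4 (up to 0.153, 0.103 and 0.1). After rescaling Ccng1 was lost without placebo library 1 or 2 or osimertinib library 3 or 5 (up to 0.0821). No member passed in the deposited CPM, over all genes or adjusted over the list alone, among 17 ERK output genes (camera adjusted p = 0.277), 15 immediate early genes (0.107) and 20 genes of the integrated stress and unfolded protein response (0.985). None passed among 14 inflammatory mediators (0.281), 16 cell cycle genes (0.0803), 25 genes of sterol and fatty acid synthesis (0.206) and 82 cytosolic ribosomal proteins (0.915). The same held for the markers of smooth muscle and pericytes (14 genes, 0.985, with a median 0.05 below that of all genes and a test direction of up), Schwann cells (5 genes, 0.0803) and erythroid cells (6 genes, 0.139). Some of these lists were called lower in fits that left out 1 library. Immediate early genes passed without placebo library 2 or osimertinib library 3 or 4 (0.00319, 0.0154 and 0.00669). Cell cycle genes passed without placebo library 2 or 4 or osimertinib library 1 or 2 (0.021, 0.0302, 0.0454 and 0.0245), and circadian clock genes without placebo library 1 or osimertinib library 4 (0.0288 and 0.0366). Erythroid markers passed without placebo library 1 or osimertinib library 3 or 5 (0.0131, 0.00676 and 8.8e-04), and Schwann cell markers without placebo library 2 or 3 or osimertinib library 4 (0.0176, 0.0253 and 0.00946). After rescaling 1 cell cycle gene was higher and 1 inflammatory gene lower. The lymphocyte, neutrophil and skeletal muscle lists had fewer than 4 tested members and were not tested.

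Among single genes, Aldh1b1, a mitochondrial aldehyde dehydrogenase gene (chromosome 4, 45799022 to 45804604), had the largest rise that met the naming rule, from 1.92 ± 0.996 to 11.5 ± 8.23 CPM. Its log2 fold change was 2.17 ± 0.32 (limma adjusted p = 3.2e-05), and 1.94 ± 0.34 rescaled (adjusted p = 0.0105). The vesicular glutamate transporter gene Slc17a7 (1.98 ± 0.31), the muscle gene Klhl40 (1.76 ± 0.31), the peptide amidating enzyme gene Pam (1.81 ± 0.35) and the ketone body enzyme gene Bdh1 (1.75 ± 0.36) also rose. Pam is also abundant in atrial muscle. The polyamine enzyme gene Odc1 (1.02 ± 0.10 rescaled, adjusted p = 0.00437), the nucleosome-binding protein gene Hmgn2 (1.13 ± 0.12 rescaled, adjusted p = 0.00443) and the arrestin-family gene Arrdc3 (1.35 ± 0.15 rescaled, adjusted p = 0.00443) had the lowest p of the rises after rescaling. The peptide transporter gene Slc15a2 (chromosome 16, 36750177 to 36784962) fell by 1.72 ± 0.38 (adjusted p = 0.00417), from 21.5 ± 21.1 to 5.40 ± 3.76 CPM. Misp (-1.42 ± 0.34), the death receptor gene Tnfrsf25 (-1.31 ± 0.32), the collagen gene Col20a1 (-1.22 ± 0.30) and Depp1 (-1.19 ± 0.36) also fell. Each of these genes lay on the same side of the placebo mean in 5 of 5 osimertinib samples. The naming rule for the largest rises and falls asked for all samples of a group on one side of the other group's mean. For genes it named, this evenness is therefore no separate support. The call of Slc15a2 was lost without placebo library 2 (adjusted p = 0.0634), that of Col20a1 without osimertinib library 5 (0.052) and that of Depp1 without placebo library 2 or 4 or osimertinib library 3 or 5 (up to 0.108). After rescaling Bdh1 passed in 3 of the 10 fits without 1 library, those without placebo library 3 or osimertinib library 1 or 4 (adjusted p up to 0.0975 in the rest). Misp was then lost without placebo library 1 or osimertinib library 3 or 5 (up to 0.0661) and Slc15a2 without placebo library 2 or osimertinib library 3 or 5 (up to 0.0725).

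**Figure D3:**
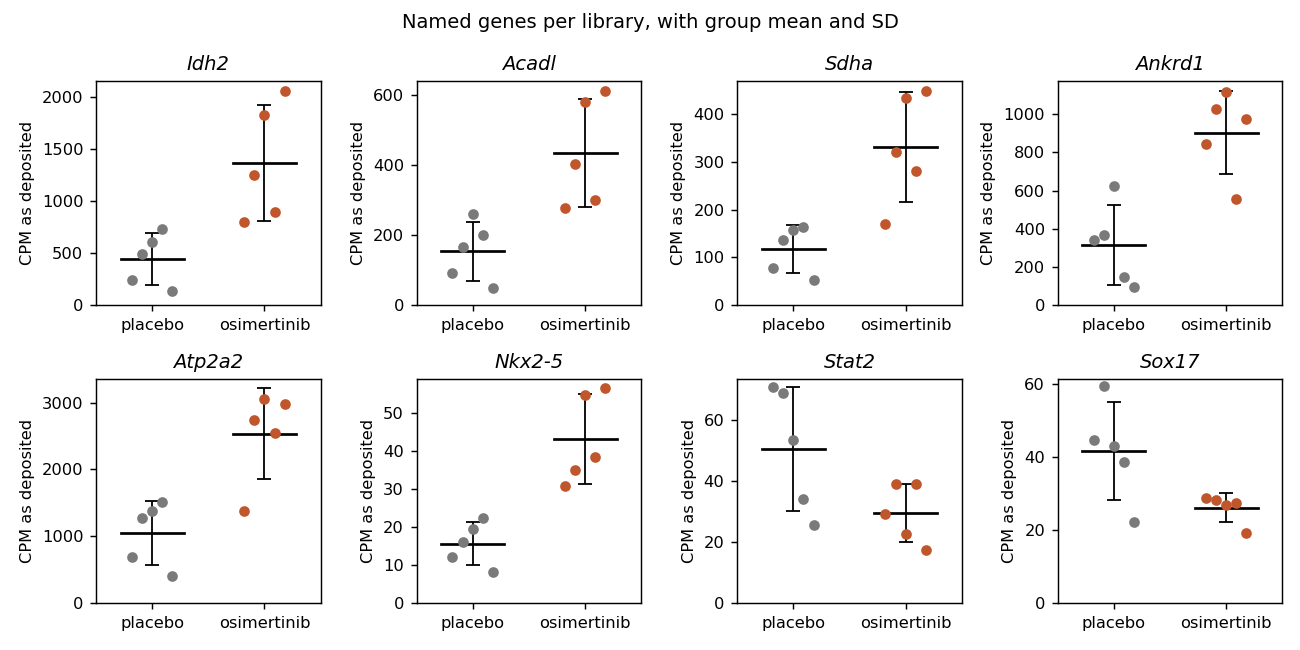
CPM as deposited of 8 named genes in each library (points), with the mean (line) and SD (bars) of the 5 libraries of each group. Idh2 has means of 444 in placebo and 1367 in osimertinib, and Stat2 of 50.6 and 29.4.

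The groups did not separate on the first principal components of the deposited CPM. The first component held 57.9% of the variance, and the differences on the first 3 had exact permutation p of 0.0952, 0.103 and 0.0794 (adjusted p = 0.103 for each). After rescaling the first component held 47.0% and separated the groups at an exact p of 0.00794, the smallest that 5 against 5 samples can give (adjusted p = 0.0238), and the next components did not (adjusted p = 0.167 and 0.317). The gap between the groups on it was narrow. Placebo libraries 3 and 4 lay at -0.02 and -0.50 and osimertinib libraries 4 and 1 at 0.79 and 0.87, while all scores ran from -43.9 to 49.3. Without placebo library 2 the first component of the deposited CPM also passed (adjusted p = 0.0476).

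In placebo library 5 the X-inactivation transcript Xist was at 68.0 CPM (1449 reads) and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 reads, which allows up to 0.141 CPM. In the other 9 libraries Xist was at 0.166 CPM or less and Ddx3y at 24.2 to 49.8 CPM. The labels give no sex, but these genes have the pattern of female tissue in placebo library 5 and of male tissue in the other 9. Sex is then not balanced between the groups. The atrial myosin light chain gene Myl7 was at 270, 74.6 and 122 CPM in placebo libraries 1, 2 and 5 and at 262, 378 and 1363 CPM in osimertinib libraries 1, 2 and 4, and was at or under 0.899 CPM in the other 4 libraries. Limits and floors cover counting error only.

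**Figure D4:**
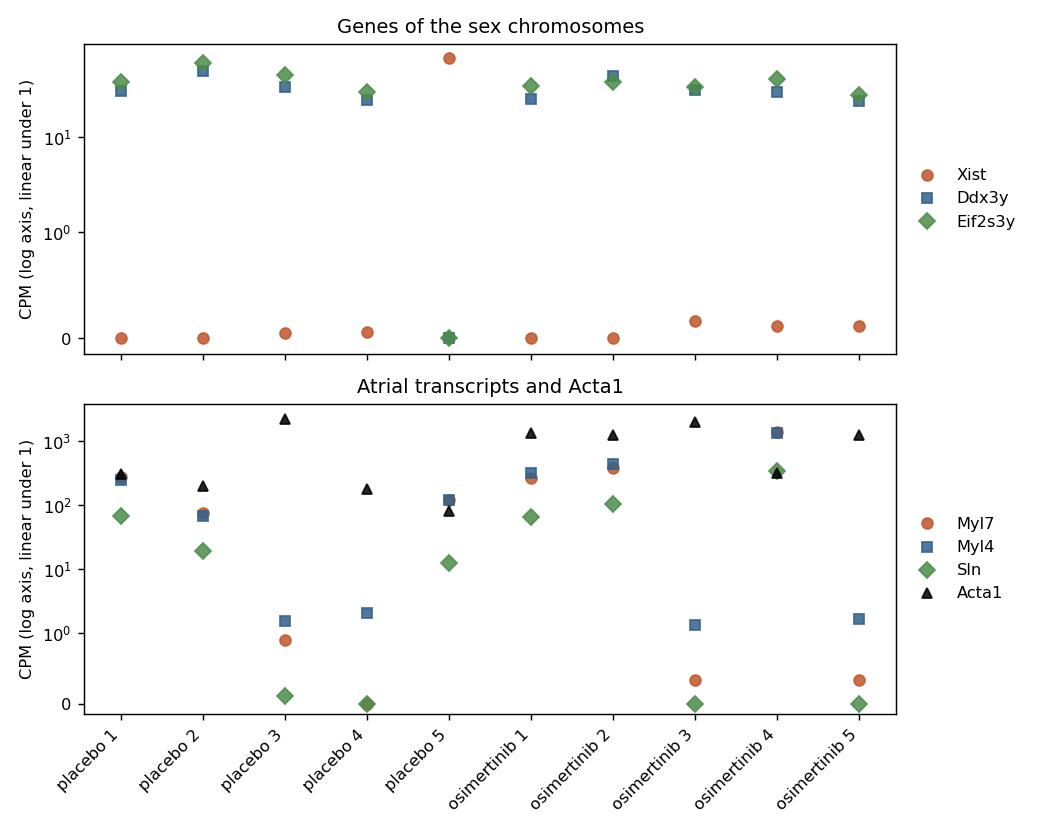
CPM as deposited, on an axis that is logarithmic above 1 and linear below, of 3 sex-chromosome genes (upper panel) and of 3 atrial transcripts and Acta1 (lower panel) in each library. Xist reaches 68.0 in placebo library 5, where Ddx3y and Eif2s3y are at 0, and Myl7 ranges from 0 to 1363.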

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

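Other than the counts of splits of the samples, the tests in this part were chosen after the results were seen. Of 288 groups of 5 values tested for a sample far from the others, 22 held one, and chance gives about 1 in 20.

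In the deposited CPM 98.1% of the 833 called genes were higher in osimertinib, and placebo library 5 lay at -124 on the first principal component, with -11.5 the nearest placebo library. That library by itself may account for part of the lean toward higher genes, since without it the median log2 fold change of all genes was 0.055, although 70.4% of the called genes were still higher. The lean depended on the scaling, since after rescaling 49.8% of the called genes were higher. In CPM without mitochondrial and haemoglobin genes it was 82.1%. Without the nuclear copies as well it was 27.9%, neither an even split nor the same lean. Whether the share of reads on mitochondrial genes and their copies is the source stays open. So does a larger amount of nuclear RNA per heart, because CPM hold no absolute amount (exact permutation p = 0.0635 for the share of other reads). Of 100 splits of the samples, 2 called as many genes, the real one included. The real split called 833 and the highest other 888, in which osimertinib library 1 took the place of placebo library 3. Since a wrong grouping called more, the count does not by itself exclude chance.

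Genes of mitochondrial metabolism were higher in osimertinib. Placebo library 5 alone is argued against by the tricarboxylic acid cycle list, whose median stayed 1.06 above that of all genes after rescaling without it, and transcript length and GC content by a median of 1.05 after their correction. These values cover that list only, which had the largest median of the lists. The oxidative phosphorylation list lay 0.63 to 1.02 above all genes in the fits of the deposited CPM without 1 library. A larger share of cardiomyocytes stays open. On its own it would lower the markers of all other cell types alike, but fibroblast markers lay 0.354 higher and endothelial markers 0.369 lower. The fibroblast minus endothelial score differed between the groups (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0397 over 5 scores). Without osimertinib library 4 the fibroblast difference was 0.22 (exact p = 0.0635) and that of the pair 0.554 (exact p = 0.00794). The score cannot exclude a larger share that came together with a shift between the other cell types. The adult sarcomere list was also higher, at a rescaled median of 0.80. Of 100 splits drawn from the 126 possible, 1, the real one, called as many genes after rescaling (2574 against 53 in the highest other). Within the splits drawn this argues against chance for that count, which covers all genes tested and not the metabolic genes alone. The number of lists gives no such argument, since 50 of 100 splits called as many (19 against 27 in the highest other). An effect of osimertinib stays open as a hypothesis, as does an uneven sampling of the ventricle. The numbers in the library names put all placebo samples before all osimertinib samples. Anything that followed this order cannot be told apart from the drug, and the labels do not say what the order stands for.

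Atrial transcripts were abundant in 6 of the 10 libraries, and Myl7 reached 1360 CPM in osimertinib library 4, with 378 the nearest osimertinib library. Atrial tissue in the sample is a candidate explanation. Over those 6 libraries the ratio of Myl4 to Myl7 kept a log2 SD of 0.175 (0.897 to 1.21) while Myl7 itself had one of 1.45. Genes that rise together in the same muscle would also keep their ratio, so it cannot tell atrial tissue from re-expression. The ratios of Sln and Mybphl to Myl7 varied more (0.545 and 0.41) and that of Dkk3 about as little (0.183), and Bmp10 was listed at 0 in all 10 libraries. Nr2f1 and Nr2f2 lay between 0.563 and 5.17 and between 3.75 and 13.4 CPM over those 6. In the libraries with little Myl7 they lay between 2.10 and 4.28 and between 5.46 and 9.09 CPM, so they do not tell the libraries apart. Re-expression in stressed ventricular muscle is argued against by 3 of the 5 libraries with the most Acta1 holding under 1 CPM of Myl7. Whether osimertinib moves Myl7 cannot be told with 5 samples per group (exact permutation p = 0.603). Dkk3, another atrial transcript, was at 199 CPM in the same library with 55.4 the nearest, and Sln at 67.2 CPM in placebo library 1 with 19.1 the nearest.

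In osimertinib library 4 the ErbB list scored 0.552 (nearest 0.0325), with Egfr at 9.15 CPM (nearest 4.27) and Erbb4 at 6.36 (nearest 2.04). The same library stood apart for Gsn at 3670 CPM (nearest 1570), Kcnh2 at 59.9 (nearest 32.5) and Arrdc3 at 53.9 (nearest 35.3). Placebo library 5 stood apart for Hmgn2 at 18.3 CPM (nearest 34.5), Odc1 at 13.4 (nearest 34.2), Sirt1 at 5.21 (nearest 12.6) and Xist at 68.0 (nearest 0.0607). Placebo library 3 held 2250 CPM of Acta1 (nearest 304) and 631 of Nppb (nearest 168), and placebo library 2 held 64.5 CPM of the potassium channel gene Kcnd1 (nearest 2.64). Osimertinib library 1 was low for Myh6 at 8760 CPM (nearest 13500), Ryr2 at 133 (nearest 250) and Odc1 at 60.3 (nearest 76.7). Sox17 was at 19.1 CPM in osimertinib library 5 (nearest 26.9) and Uty at 14.9 in osimertinib library 2 (nearest 8.07).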

How the results depend on the processing

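The fits after rescaling with a further change, voom on estimated reads, CPM without the nuclear copies and the fits without a library after rescaling were chosen after the data were seen. Counting error limits genes near 1 CPM, which is 15.9 to 21.3 reads per library, and the planned edgeR and voom tests on whole reads were not run because the reads did not come out whole. Where no reason is given, the cause was not tested.

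The count of called genes was 833 (817 higher, 16 lower). With no filter limma called 0 (0 higher, 0 lower), with 3269 genes at an unadjusted p under 0.05, while the prior fell to 5.15 degrees of freedom. It was 2574 (1283 and 1291) after rescaling, 2654 (1224 and 1430) after quantile normalization, 625 (513 and 112) without mitochondrial and haemoglobin genes, and 2579 (2159 and 420) with array weights. A pseudocount of 0.1 gave 10 lower genes. After rescaling it was 2225 (1012 and 1213) without placebo library 5, 4704 (2589 and 2115) with the atrial covariate and 2642 (1332 and 1310) with the length and GC correction. Voom gave 2633 (1315 and 1318), and CPM without mitochondrial genes, their copies and haemoglobin genes 2400 (670 and 1730). Leaving out 1 library gave 307 to 1126 genes, 301 to 1118 higher and 5 to 238 lower, and after rescaling 512 to 2807, 213 to 1566 higher and 299 to 1362 lower.

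Whether replicate numbers pair the samples cannot be told from the values. Same-numbered samples correlated at 0.429, 0.251, 0.466, -0.334 and -0.175. The highest correlations of the same placebo samples with another number were 0.416, 0.0605, 0.424, 0.528 and 0.339. Numbers 1, 2 and 3 thus correlated best with their own number, and 4 and 5 did not. With the replicate number as a block 1320 genes were called (1286 and 34), and 2949 (1594 and 1355) after rescaling, and the components had adjusted p of 0.125.

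Of 37 lists 19 were called, 16 higher and 3 lower. With an estimated correlation 0 were called (0 higher, 0 lower), and with fry 0 (0 higher, 0 lower). Array weights called 10 higher, and leaving out 1 library gave 3 to 6 lower. The first component passed after rescaling (adjusted p = 0.0238) and the second with genes scaled to unit variance (0.0238), and the first ranged from 0.0476 to 0.294 without 1 library.

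Some results changed direction in settings in which they did not pass. The difference in haemoglobin share was -0.00653 percentage points without mitochondrial genes and -0.00765 to 0.00612 without 1 library. Log2 fold changes turned for Erbb2, Hdac5 and Kcnh2, in that order -0.14, -0.098 and -0.036 after rescaling. They were -0.17, -0.19 and -0.062 after quantile normalization, -0.12, -0.075 and -0.011 without mitochondrial and haemoglobin genes, -0.13, -0.11 and -0.018 with voom. They were -0.22, -0.12 and -0.12 with the atrial covariate, -0.34, -0.30 and -0.23 without the copies as well, and -0.14, -0.098 and -0.036 with the block after rescaling. Erbb2 and Hdac5 were at -0.032 and -0.028 after rescaling without placebo library 5. With the atrial covariate Myl4 and Myl7 were at -0.0017 and -0.22. Hdac3 was at -0.012 after quantile normalization. Without the copies as well, Erbb3, Hdac2, Hdac3 and Hdac9 were at -0.0053, -0.029, -0.18 and -0.039. Without 1 library Postn ranged from -0.53 to 0.24, Hdac1 from -0.21 to 0.15, Hdac4 from -0.17 to 0.14, Hdac7 from -0.39 to 0.016 and Myl7 from -0.14 to 2.54.

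The direction of camera changed for lists whose medians, relative to all genes, follow. Cytosolic ribosomal proteins passed as lower after quantile normalization (-0.11, adjusted p = 0.0147) and with the length and GC correction (-0.17, adjusted p = 4.2e-05). Uncalled, they were at -0.046 with array weights, 0.019 at a mean of 5 CPM, 0.0016 after rescaling and with the block after it, and 0.030 with the block. They were at -0.020 with voom, 0.0020 without mitochondrial and haemoglobin genes, -0.0088 without the copies as well and -0.044 to 0.075 without 1 library. The extracellular matrix list was at 0.021 after rescaling, 0.21 with no filter, 0.029 after quantile normalization. It was at 0.11 with the length and GC correction, 0.042 with the block, 0.011 with voom, 0.013 without the copies and -0.082 to 0.16 without 1 library, where it passed as higher without placebo library 1 or osimertinib library 5. Smooth muscle markers were at -0.063 with array weights, -0.063 at a mean of 5 CPM, -0.044 after rescaling and with the block after it, -0.072 after rescaling without placebo library 5. They were at -0.052 and -0.024 at pseudocounts of 0.1 and 2, -0.036 after quantile normalization, -0.065 with voom, -0.047 without mitochondrial and haemoglobin genes, -0.050 without the copies and -0.097 to 0.057 without 1 library. The integrated stress list was at -0.045 after rescaling, -0.0094 with the atrial covariate, -0.050 with voom, 0.14 with no filter and -0.094 to 0.096 without 1 library. With no filter the ErbB, acetyltransferase and deacetylase lists were at 0.12, 0.081 and 0.15. Without 1 library erythroid markers ranged from -0.68 to 0.036 and epicardial markers from 0.017 to 0.28.

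Fry asks about 0 and not about other genes, and its direction was up for 11 uncalled lists that camera put lower. For erythroid markers, whose own median was -0.07, the comparison with 0 does not account for this, and the cause was not tested. Their medians relative to all genes, the same in both tests, were -0.13 for ERK output, -0.22 for cell cycle, -0.063 for circadian clock, -0.34 for erythroid, and 0.042 for extracellular matrix genes. They were -0.095 for acetyltransferase, -0.029 for deacetylase, -0.21 for immediate early, -0.12 for inflammatory, -0.019 for integrated stress and -0.19 for p53 genes.

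Of 89 named genes, 52 were called in the deposited CPM. After rescaling 64 kept direction and side of the threshold, 7 lost their call, 15 gained one and 3 turned. With no filter 52 lost theirs. Over the 10 fits without 1 library 787 of the gene results kept both, 66 lost a call, 21 gained one and 16 turned, and of the list results 322, 11, 18 and 19.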

Other observations

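The fits with atrial transcripts as a covariate and without placebo library 5 after rescaling were chosen after the data were seen.

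Libraries of a group differed in their scores on the metabolic lists, given as mean log2 rescaled and centred over the 10 libraries. The oxidative phosphorylation list scored -1.14, -0.65, 0.31, 0.27 and -0.74 in placebo libraries 1 to 5, where Myl7 was at 270, 74.6, 0.899, 0 and 122 CPM. It scored 0.09, 0.27, 0.67, 0.06 and 0.86 in osimertinib libraries 1 to 5, where Myl7 was at 262, 378, 0.332, 1363 and 0.333 CPM. The tricarboxylic acid cycle list scored -1.19, -0.76, -0.07, -0.0018 and -0.70 in placebo and 0.02, 0.42, 1.02, 0.10 and 1.16 in osimertinib, in the same order of libraries. With the level of atrial transcripts as a covariate after rescaling, 4704 genes were called, 2589 higher and 2115 lower, against 2574 without it.

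Xist at 68.0 CPM with no reads of the Y-linked genes set placebo library 5 apart from the other 9. This is the pattern of female tissue, and that of the other 9 is the pattern of male tissue, although the labels give no sex. An effect of sex cannot be separated from other traits of this library, and none was tested. Without that library after rescaling 2225 genes were called, 1012 higher and 1213 lower.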
